A study of Anopheles gambiae with 12 samples.

How the data were processed

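Midguts and salivary glands of infected Anopheles gambiae females were sampled on days 7 and 14, per the labels. For ATAC-seq, about 20 mosquitoes per sample gave 25 to 37 M paired-end reads of 50 bp. For RNA-seq, about 30 midguts or 60 salivary glands gave strand-specific, ribosome-depleted libraries read over 75 bp. The submitters name Bowtie2 2.4.1, SAMtools 1.10, MACS2 2.1.2, bedtools, HOMER 4.11, ChIPseeker 1.22, STAR 2.7.3a and DESeq2 1.26, and other settings are not given in the sources used here.

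The values analysed were those of the deposited tables, which give peaks called per tissue and infection. The summary table of the authors gives the number of peaks and of annotated genes per list. The peak table gives, per the file headers, the Peak FoldChange, a ratio over the peak caller's background at the summit, and the Q-value as -log10. It also gives the authors' annotation class and gene for each peak, and midgut histone mark peaks that the header credits to Ruiz et al. The expression columns give normalized counts by the authors, a signal per gene and library, repeated on each peak of the gene. Genes without a peak are therefore not in the table. The genome build and whether starts count from 0 or 1 are not given in the sources used here, and coordinates are printed as the table gives them.

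The labels list single-end and paired-end RNA-seq samples, while the expression columns name only tissue and infection, so each column was placed with the single-end samples as a stand-in. Every expression value was checked to be a whole multiple of 1 read within 0.02 reads. A read was worth 1.18 and 1.03 in the midgut libraries of infections 2 and 3, and 0.611 and 1.33 in the salivary gland libraries, which sets the finest step at low counts. On 2286 peaks in 5' UTRs the expression belonged to the gene named by HOMER and not to the final gene (2096 matched the former, 0 the latter and 190 could not be checked), so these values were left out. Expression was used for 11304 genes. There were 3 symbols turned into dates, which were set back to AGO1, AGO2 and AGO3.

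Peak lists were compared by overlap of at least 1 bp, with 100 random placements within chromosomes. A region counted as restricted when it was in both lists of a tissue and overlapped neither list of the other. Classes and gene lists were compared with two-sided Fisher's exact tests, adjusted by Benjamini and Hochberg over 14 and 30 tests. The background was the 12149 genes with a peak. Intervals on shares are 95% Wilson intervals. Intervals on shares and odds ratios, and floors, cover counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

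RNA levels were compared as salivary glands minus midguts with limma 3.58.1 in R 4.3.3, on log2 of the normalized count plus 1 with a mean-variance trend, for 9885 genes at 10 or more in at least 2 libraries, at a threshold of 0.05 after Benjamini-Hochberg adjustment. This test, its alternatives, the comparison of RNA with restricted regions and the histone mark and pathway tests were not planned and were chosen after the data were seen. Gene lists were tested with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Fry was made the main list test after the results of camera had been seen. Reads recovered from the values were tested with edgeR 4.0.16 and DESeq2 1.42.0. Tested on simulated data, limma found 83 of 100 genes changed by 2 log2 units and 6 of 100 changed by 1. It made 2 false calls among 9571 genes, and edgeR found 81 and 7, with 2 false calls. The simulation changed 200 genes and gave every gene the same dispersion, while 3999 of 9885 genes were called in the data. Its shares found and its false calls therefore do not carry over to the data. Both expression libraries of a tissue correlated at 0.976 in midguts and 0.964 in salivary glands.

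Infection number marks a shared experimental infection and was tried as a block. Deviations of midguts and salivary glands from their tissue means correlated within infections at 0.148 (Pearson) and 0.267 (Spearman) over 9885 genes. With 2 lists or libraries per tissue no sample was tested as an outlier.

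The peak comparisons, their alternatives, the names of 15 gene lists and the rule for named genes were fixed before the data were examined. The patterns that matched list members to gene names were written afterwards, and GATAe, Sox21a and Scr were left out as ambiguous. The lists were digestion and midgut, saliva proteins, salivary gland secretory regulators, antimicrobial peptides and lysozymes, complement-like genes, CLIP proteases with serpins and prophenoloxidases, immune signalling, haemocyte, muscle, fat body and neuronal markers, chemosensory receptors, housekeeping, Hox and patterning, and detoxification. The rule names, in each tissue, the 10 genes with the most restricted regions, the 10 restricted regions with the highest fold, the 10 regions of all lists with the highest rank, and list members with a restricted promoter region. Naming the 10 largest RNA changes per direction, and the list members and small counts outside the rule, was chosen after their values were seen.

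Alternatives for the peaks were a reciprocal overlap of 50%, the upper part of each list by fold, equal list sizes, comparison within infections, promoter regions only, 4 bins of peak number and each list left out. The upper part was taken in both tissues, so a region restricted in that setting may overlap a weaker peak of the other tissue. Alternatives for RNA were pseudocounts of 0.5 and 5, no filter, no trend, the block, edgeR, DESeq2 and each library left out. A test of each peak was not run, since the table gives no counts per peak and sample. Classes from a reference annotation were not assigned, since no reference of the same build was used here.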

Results

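Open chromatin and RNA were measured in midguts and salivary glands of female Anopheles gambiae mosquitoes of the Kisumu strain that had been infected with the malaria parasite Plasmodium falciparum 3D7. ATAC-seq, which maps open chromatin by the insertion of a transposase, gave 4 peak lists, 1 for each tissue in infections 1 and 2 (n = 2 per tissue). RNA-seq gave 4 libraries of normalised counts, 1 for each tissue in infections 2 and 3 (n = 2 per tissue). Midguts were taken on day 7 and salivary glands on day 14, so tissue and day could not be separated in any comparison below.

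The midgut lists held 40529 peaks in infection 1 and 53392 in infection 2, covering 6.02 and 7.90 Mb. The salivary gland lists held 51703 and 47381 peaks, covering 10.95 and 11.14 Mb. Median peak width was 99 and 101.5 bp in midguts, and 134 and 157 bp in salivary glands. The median fold over the peak caller's background was 4.90 and 4.23 in midguts, and 5.53 and 6.74 in salivary glands. The RNA values corresponded to 19.4 and 26.7 M reads for midguts of infections 2 and 3, and to 33.1 and 17.7 M reads for salivary glands. A list holds only peaks past the caller's threshold, and the depth behind each peak list is not given in the sources used here. The 95% intervals on shares below are Wilson intervals, and intervals on shares and odds ratios cover counting error only.

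The 1st comparison asked how much of the open chromatin the tissues share. Among regions present in all 4 lists, the highest-ranked region of a nuclear chromosome lay in an intron of the homeobox gene HEX (AGAP001389, chromosome 2R, 4134187 to 4134416). HEX is known as a developmental transcription factor, and its region reached folds of 208 and 209 in midguts and 264 and 285 in salivary glands. Its RNA was too low to test, at normalised counts of 3.55 and 1.03 in midguts and 0.611 and 1.33 in salivary glands. Of the 10 highest-ranked regions, 6 lay on the mitochondrial genome, at genes such as ND1 and COX1 of the respiratory chain. Each salivary gland list holds 1 mitochondrial peak, so these 6 regions are a single peak there.

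The salivary gland lists overlapped each other most. Averaged over both directions, 77.4% of peaks overlapped by at least 1 bp between the salivary gland lists and 54.3% between the midgut lists. The 4 pairs of lists from different tissues overlapped by 47.8% to 52.1%, and random placement gave 6.57% to 7.58% for these pairs, 5.63% for the midgut pair and 8.52% for the salivary gland pair. By covered bases (Jaccard index) the salivary gland lists shared 66.5%, the midgut lists 42.5% and lists of different tissues 31.1% to 33.2%. Counted by peaks in one direction the order turned: of the midgut peaks of infection 2, 46.3% were met by the other midgut list, and 48.7% and 49.1% by the salivary gland lists of infections 1 and 2. The number of peaks per gene correlated across 12149 genes between tissues (Spearman 0.698), and between the lists of a tissue at 0.798 in midguts and 0.888 in salivary glands. The value between tissues used the mean of the lists of each tissue, while the values within a tissue used single lists. With a list left out, the value between tissues was 0.665 to 0.692. Genes are not independent replicates. A promoter peak was found in both lists for 39.7% of genes in midguts (95% interval 38.8% to 40.6%) and for 51.8% in salivary glands (50.9% to 52.7%). The 4 lists can be split into pairs in 3 ways, so an exact test could not go below p = 0.333.

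**Figure D1:**
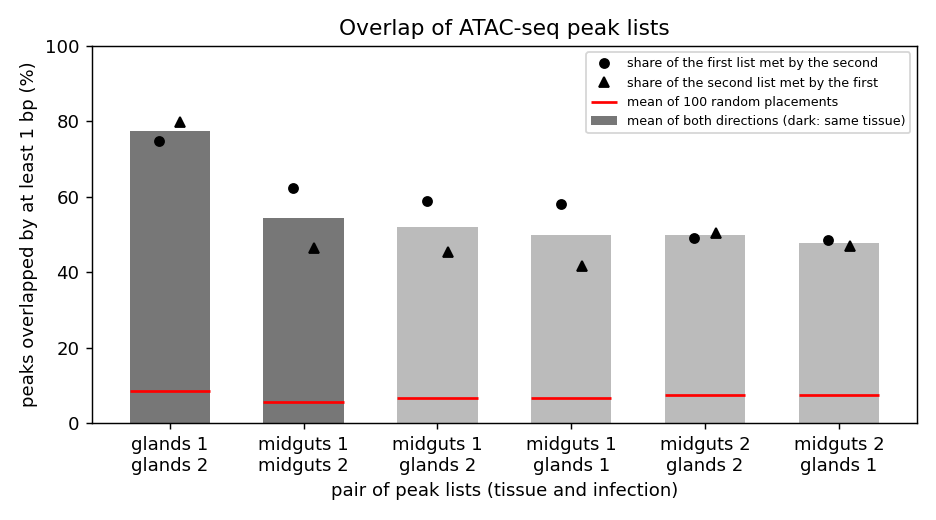
Overlap of each pair of ATAC-seq peak lists, as the share of peaks (%) met by at least 1 bp of the other list. Bars are means of both directions, points the single directions and red lines the mean of 100 random placements; the salivary gland pair reached 77.4% and the midgut pair 54.3%.

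Tissue-restricted open regions were those found in both lists of a tissue and in neither list of the other. Midguts had 4095 such regions, 16.9% of the 24186 found in both midgut lists (95% interval 16.5% to 17.4%), assigned to 2793 genes. Salivary glands had 12452, 34.6% of 36039 (34.1% to 35.0%), assigned to 5095 genes. Restricted regions were weaker than shared ones, with a median fold of 4.26 against 7.03 in midguts and 5.52 against 13.3 in salivary glands. Both shares rested on agreement between the lists of a tissue. Without the midgut list of infection 1 or 2 the midgut-restricted regions numbered 25136 or 15185, and without the salivary gland list of infection 1 or 2 the gland-restricted regions numbered 20545 or 24340.

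Restricted regions differed from shared ones in their classes of the genome, and whether the tissues differed in this was not tested. In midguts, exons held 40.4% of restricted and 3.30% of shared regions (odds ratio 19.8, 95% interval 17.9 to 22.0), and promoters held 6.03% of restricted and 30.5% of shared regions (odds ratio 0.146, adjusted p = 4.4e-284, Fisher's exact test). In salivary glands, distal intergenic sequence held 32.0% of restricted and 21.2% of shared regions (odds ratio 1.76, adjusted p = 7.0e-98, Fisher's exact test) and introns held 37.6% and 29.6% (odds ratio 1.44, adjusted p = 5.1e-48). Distal intergenic sequence was commoner among restricted regions of midguts too, at 26.1% against 20.8% (odds ratio 1.34, adjusted p = 4.3e-13, Fisher's exact test). With the upper part of each list these odds ratios were 2.01 in midguts and 2.04 in salivary glands. Promoters were rarer among gland-restricted regions too, at 15.8% against 31.9% (odds ratio 0.399). Gland-restricted regions were exonic in 4.99% of cases and shared ones in 3.04% (odds ratio 1.67, and 3.41 without the salivary gland list of infection 2). The exonic odds ratio of midguts was 11.3 without that list, 10.3 with a reciprocal overlap of 50% and 10.2 with only the upper part of each list by fold. Introns were rarer among midgut-restricted regions (odds ratio 0.585), but with only the upper part of each list by fold this turned to 1.35, and with a reciprocal overlap of 50% to 1.29. Of the other classes, 5' UTRs were rarer among restricted regions in midguts (odds ratio 0.187) and salivary glands (0.512), and 3' UTRs were commoner among those of midguts (2.89, or 5.62 with the upper part of each list). With the reciprocal overlap the 5' UTR values were 0.722 and 0.787, and that of midgut promoters was 0.263. Among midgut-restricted regions the exonic share was 48.1% in the lowest and 22.3% in the highest of 4 equal bins by fold. Tests were two-sided and adjusted over 14 classes and tissues. Regions are features of the genome and not replicates, so each p describes these lists.

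**Figure D2:**
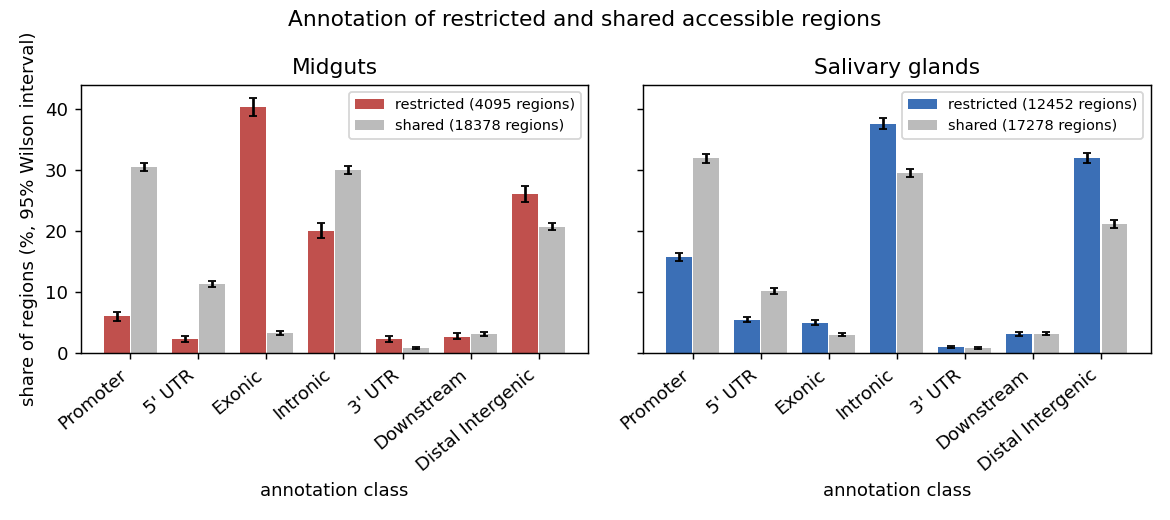
Share of restricted and shared accessible regions (%) in each annotation class, for midguts (left) and salivary glands (right), with 95% Wilson intervals as bars. Exons held 40.4% of midgut-restricted regions and 4.99% of gland-restricted ones.

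The next question was which genes carried the restricted regions. In midguts, 15 of 35 genes of digestion and the gut had a restricted region (42.9%, against 23.0% of all genes with a peak; odds ratio 2.52, 95% interval 1.29 to 4.93). Promoters made the contrast larger, with a midgut-restricted promoter region at 11 of the 35 genes (odds ratio 24.3, adjusted p = 9.3e-10, Fisher's exact test). Among them were APN1, a gut surface aminopeptidase (2L, 3797193 to 3797574, folds 6.21 and 9.66), CHYM1, a chymotrypsin (2L, 37119809 to 37120107, folds 6.86 and 8.15), Aper1, a peritrophin of the peritrophic matrix (2L, 38568684 to 38568954, folds 10.5 and 10.6), and the gut homeobox gene caudal (3R, 37550336 to 37550609, folds 5.56 and 5.73). The list as a whole had adjusted p = 0.0440 (Fisher's exact test) and 0.0718 when tissues were compared within infections. Its call was lost without any single list, with adjusted p of 0.101 and 0.0659 without midguts of infections 1 and 2, and 0.0856 and 0.102 without salivary glands of infections 1 and 2.

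Other gene groups departed from the background in the regions restricted to one tissue. Of 7 Hox and patterning genes, 5 had a midgut-restricted region (odds ratio 8.39, adjusted p = 0.0440, Fisher's exact test, and 0.0575 within infections). That call was lost without midguts of infection 1 (odds ratio 2.901, adjusted p = 0.644) and without salivary glands of infection 1 (0.0863) or 2 (0.102). Housekeeping genes such as those of the ribosome had few midgut-restricted regions, at 12 of 121 genes (odds ratio 0.366, adjusted p = 0.0044). Chemosensory receptors and odorant-binding proteins had few gland-restricted regions, at 34 of 185 genes against 41.9% of all genes (odds ratio 0.307, adjusted p = 2.7e-10). Gland-restricted regions were also fewer at complement-like genes (8 of 38, odds ratio 0.368, adjusted p = 0.0440, and 0.0575 within infections) and at detoxification genes (67 of 207, odds ratio 0.658, adjusted p = 0.0440, and 0.0560 within infections). The detoxification call was lost without salivary glands of infection 1 (adjusted p = 0.117) or 2 (0.911). With genes compared in 4 bins of peak number, digestion in midguts (odds ratio 3.23) and chemosensory genes in salivary glands (0.528) stayed past the threshold, chemosensory genes in midguts joined them (2.01), and the other calls were lost. The remaining list tests of the 30, saliva proteins in salivary glands (11 of 25 genes) and antimicrobial peptides (6 of 13) among them, did not pass.

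In salivary glands the gene with the most restricted regions was the histone methyltransferase gene MLL1 (AGAP002741), with 25 of its 34 regions. Other such genes were a POU class 3 transcription factor (AGAP005878, 22 of 27), an Mpv17-like protein (AGAP004046, 23 of 45) and yorkie, the effector of Hippo growth control (AGAP006045, 19 of 32). In midguts the CDC-like kinase gene AGAP000847 had 10 restricted regions among 21 (and 6 gland-restricted among 22), AGAP000938 had 9 among 10 and Tartan (AGAP011378) had 9 among 13. Doublesex (AGAP004050), the sex determination factor, had 7 among 29, and 6 gland-restricted among 28. Of the 10 genes with the most gland-restricted regions, 9 were tested in RNA, and 5 of these were higher in salivary glands and 0 in midguts (limma). Of the 10 genes for midguts, 3 were higher in midguts and 4 in salivary glands. The POU gene had a log2 fold change (salivary glands minus midguts) of 4.93 ± 0.31 (SE, n = 2 per tissue), yorkie 1.55 ± 0.26, the CDC-like kinase gene 1.53 ± 0.26 and AGAP000938 4.70 ± 0.68.

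The strongest midgut-restricted region lay in an intron of growth factor independent 1 (AGAP009699, 3R, 39059314 to 39060127, folds 11.4 and 11.2), a zinc finger regulator, whose RNA was higher in midguts (-2.89 ± 0.53, and -2.07 or -3.71 without the gland library of infection 2 or 3). Promoter regions followed at Aper1, at AGAP006432 (2L, 31788470 to 31789404, folds 9.48 and 11.5) and at Niemann-Pick C1, a sterol transporter (AGAP000579, X, 10176512 to 10177144, folds 10.1 and 9.36). RNA of AGAP006432 (-9.55 ± 0.85) and Niemann-Pick C1 (-7.56 ± 0.57) was higher in midguts. Without the gland library of infection 2 or 3 these were -11.12 or -7.99 and -8.42 or -6.70. In salivary glands, the strongest restricted regions on assembled chromosomes were the promoter of AGAP006063 (2L, 25949886 to 25950242, folds 20.7 and 41.3) and an intron of AGAP008322 (3R, 9114853 to 9115828, folds 25.0 and 36.4). RNA of AGAP006063 (5.62 ± 0.24) and AGAP008322 (4.36 ± 0.34) was higher in salivary glands. The other 8 of the 10 strongest lay on UNKN, the assembly's collection of unplaced sequence. It held 88.7% of the strongest 1% of gland-restricted regions (110 of 124, 95% interval 81.9% to 93.2%) but 6.44% of all gland-restricted regions (802 of 12452), and 2.33% of the gland regions shared with midguts.

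The RNA comparison asked which genes differed between the tissues. Salivary proteins stood highest in salivary glands. SG3 (log2 fold change 11.12 ± 0.23, adjusted p = 6.9e-07, limma), SG2 (11.03 ± 0.23, adjusted p = 6.9e-07), D7r1, which binds host amines (11.35 ± 0.84), SG1b (11.20 ± 0.50) and the antigen 5 proteins A5R1 (11.20 ± 0.39) and A5R2 (11.18 ± 0.52) were among the 10 largest changes (SE, n = 2 per tissue). Without the midgut library of infection 2 or 3, D7r1 stood at 10.04 or 12.66, SG1b at 10.36 or 12.04 and A5R1 at 10.61 or 11.78, and without the gland library of infection 2 or 3 D7r1 stood at 12.03 or 10.67. Among the 10 largest changes in midguts were the chymotrypsins CHYM2 (-11.31 ± 1.42, adjusted p = 0.00062, limma) and CHYM1 (-10.35 ± 1.12). The largest change was at AGAP013137, a gene without a description (-11.39 ± 1.39). The gland libraries of infections 2 and 3 differed here, at normalised counts of 37.9 and 0 for CHYM2, 39.7 and 1.33 for CHYM1, and 35.5 and 0 for AGAP013137. Without the gland library of infection 2 or 3, CHYM2 stood at -13.95 or -8.66, CHYM1 at -12.42 or -8.28 and AGAP013137 at -13.98 or -8.79. Of 9885 genes tested, 2355 were higher in salivary glands and 1644 in midguts at an adjusted p below 0.05 (limma), and 4790 had an unadjusted p below 0.05. With infection as a block the counts were 2570 and 2172. The midgut count fell to 1068 without salivary glands of infection 2 and to 1046 without those of infection 3. No gene was called in the opposite direction under any alternative.

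Of 25 saliva proteins, 24 were higher in salivary glands and 0 in midguts (24 and 0 adjusted over the list alone), with a median log2 fold change of 10.40, or 9.74 without salivary glands of infection 3 and 9.80 with a pseudocount of 5. The list had adjusted p = 0.0048 with limma's fry. Camera, another test of limma, which compares a list with all other genes, gave adjusted p = 0.235 with an estimated correlation. That estimate rests on 2 libraries per tissue, and with it camera called 0 of the 15 lists. With a preset correlation of 0.01 camera gave adjusted p = 5.3e-18 for saliva proteins and called 9 lists. The others were the digestion, complement-like, CLIP, antimicrobial, fat body, haemocyte, neuronal and housekeeping lists, with camera's adjusted p up to 0.00023. Of 27 genes of digestion and the gut, 17 were higher in midguts and 3 in salivary glands (17 and 4 adjusted over the list alone, 17 and 5 with infection as a block), with a median of -7.42, or -1.98 over all 35 members without the filter on low values. They included the trypsin gene TRYP1 (-7.66 ± 0.46), APN1 (-10.11 ± 0.80), Aper1 (-5.19 ± 0.27) and caudal (-7.74 ± 0.54). Without the gland library of infection 2 or 3, TRYP1 stood at -8.42 or -6.90, APN1 at -11.58 or -8.64 and caudal at -8.51 or -6.97. The 3 higher in salivary glands were a late trypsin (AGAP007165, 4.28 ± 0.74, and 5.49 or 3.07 without the midgut library of infection 2 or 3), cathepsin F (AGAP002879, 1.29 ± 0.23), a lysosomal protease, and a cathepsin B precursor (AGAP004534). For this list fry gave adjusted p = 0.0157, or 0.0711 with infection as a block, and camera gave adjusted p = 0.361 with an estimated correlation. Low levels of midgut transcripts were read in the gland library of infection 2, at a median of 0.302% of their midgut level over 37 abundant midgut genes. These genes were picked for standing below 0.2% in the gland library of infection 3, where their median was 0.0319%.

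Immune genes were mostly higher in salivary glands. Of 34 complement-like genes, 25 were higher there and 1, LRIM6 (-4.32 ± 0.28), in midguts (26 and 1 adjusted over the list alone, and 2 in midguts without midguts of infection 2), with a median log2 fold change of 4.53. The thioester protein TEP1 (5.45 ± 0.31, n = 2 per tissue), which binds ookinetes, its partners LRIM1 (5.44 ± 0.42, and 4.79 or 6.09 without the midgut library of infection 2 or 3) and APL1C (5.32 ± 0.23), and LRIM12 (8.54 ± 0.39) were in this group. Of 71 CLIP proteases, serpins and prophenoloxidases, which act in melanization, 60 were higher in salivary glands and 2 in midguts (62 and 2 adjusted over the list alone). The median was 4.53, or 4.48 with the 2 genes absent from midguts at their bounds and 3.80 with a pseudocount of 5. CLIPA9 (5.501 ± 0.23), CLIPA7 (4.91 ± 0.23) and SRPN2, an inhibitor of melanization (4.94 ± 0.25), were higher in salivary glands. CLIPE6 was at least 69.5-fold and CLIPB12 at least 12.0-fold higher, since both were at 0 in the midgut libraries, taken as 3 reads per library. The 2 higher in midguts were SRPN10 (-0.96 ± 0.20) and PPO1 (-2.96 ± 0.86, and -2.16 or -3.76 without the midgut library of infection 2 or 3). The PPO1 call was lost without midguts of infection 2 (adjusted p = 0.187, limma) and without salivary glands of infection 2 (0.0699) or 3 (0.0537). With fry the complement-like list had adjusted p = 0.0048 and the CLIP list 0.0029. Camera gave adjusted p = 0.1996 for the former and adjusted p = 0.157 for the latter with an estimated correlation.

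Of 11 antimicrobial peptide and lysozyme genes, 9 were higher in salivary glands and 0 in midguts (10 and 0 adjusted over the list alone), with a median of 2.17. Lysozyme LYSC1 (4.97 ± 0.27), gambicin GAM1 (2.17 ± 0.23) and defensin DEF1 (2.18 ± 0.32) were among them. The count was 5 without salivary glands of infection 2. With fry the list had adjusted p = 0.0109, or 0.0655 with infection as a block, and with camera adjusted p = 0.277 with an estimated correlation. Of 34 immune signalling genes, 12 were higher in salivary glands and 4 in midguts (13 and 4 adjusted over the list alone), and the salivary gland count was 7 without salivary glands of infection 2 or of infection 3. TOLL5A (4.77 ± 0.39) and SOCS, a brake on JAK-STAT signalling (1.82 ± 0.22), were higher in salivary glands. The 4 in midguts were TOLL9 (-2.37 ± 0.35), TRAF6 (-1.66 ± 0.24), MYD and ikk2. This list had a median of 0.12, adjusted p = 0.0157 with fry and, with camera, adjusted p = 0.616 with an estimated correlation.

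Markers of other cell types moved with the immune groups. All 6 fat body genes tested were higher in salivary glands (6 adjusted over the list alone), with a median log2 fold change of 5.18, or 4.61 and 5.91 without midguts of infection 2 and 3. The lipid carrier lipophorin (Lp, 6.75 ± 0.21), transferrin (Tsf1, 6.14 ± 0.44) and the yolk protein vitellogenin (Vg, 4.42 ± 0.25) were among them. Without the midgut library of infection 2 or 3, Tsf1 stood at 5.45 or 6.83. Of 16 haemocyte genes, 12 were higher in salivary glands and 1, PPO1, in midguts (12 and 1 adjusted over the list alone), with a median of 2.74. The PPO1 call was lost without midguts of infection 2 or salivary glands of infection 2 or 3, leaving 0. Higher in salivary glands were the phagocytosis receptor genes NimB2 (3.14 ± 0.37) and SCRB3 (3.92 ± 0.48, and 4.64 or 3.20 without the gland library of infection 2 or 3). The lists share genes: the haemocyte list holds prophenoloxidases of the CLIP list and TEP1, LRIM15, LRIM16A and LRIM17 of the complement-like list, and LRIM1 is also in the fat body list. Of 10 neuronal genes, 8 were higher in salivary glands and 0 in midguts (8 and 1 adjusted over the list alone), with a median of 4.61. The midgut count was also 1 without midguts of infection 2 and with infection as a block. The GABA receptor gene Rdl (6.71 ± 0.35), ChAT, which makes acetylcholine (5.73 ± 0.36), and the sodium channel gene para (4.09 ± 0.27) were among these. With fry the fat body and neuronal lists had adjusted p = 0.0048 and the haemocyte list 0.0050. With infection as a block the fat body and haemocyte lists each had 0.0522. Camera gave the fat body and haemocyte lists each adjusted p = 0.1996 and the neuronal list adjusted p = 0.235 with an estimated correlation. Of 14 muscle genes, 3 were higher in salivary glands, such as a troponin C (AGAP006178, 5.95 ± 0.73, and 4.91 or 6.99 without the midgut library of infection 2 or 3), and 4 in midguts, such as troponin T (AGAP002350, -2.07 ± 0.31). Over the list alone these were 3 and 5, and without salivary glands of infection 3 they were 1 and 7. Without salivary glands of infection 2, or without the mean-variance trend, the midgut count was 2. The muscle median was -0.68 and the mean 0.10, and the list did not pass (adjusted p = 0.956, fry).

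Housekeeping genes were shifted the other way, by smaller amounts. Of 116 tested, 51 were higher in midguts and 4 in salivary glands (52 and 5 adjusted over the list alone), with a median of -0.62. The ribosomal gene RpLP1 was at -1.83 ± 0.31, and an alpha-tubulin gene (AGAP010971) was among the 4 at 3.48 ± 0.28. The midgut count was 29 without midguts of infection 3, 6 without salivary glands of infection 2 and 12 without those of infection 3, where the salivary gland count was 2. It was 81 with infection as a block (limma) and 29 without the mean-variance trend. With fry the list had adjusted p = 0.0095, or 0.0522 with the block, and with camera adjusted p = 0.1996 with an estimated correlation. Of 171 detoxification genes, 56 were higher in salivary glands and 53 in midguts (56 and 55 adjusted over the list alone). The cytochrome P450 genes CYP4AA1 (8.12 ± 0.33) and CYP4H24 (-8.76 ± 0.45, and -9.39 or -8.12 without the gland library of infection 2 or 3) lay at the extremes. The detoxification median was 0.16, with adjusted p = 0.0144 upward by fry and, with camera, adjusted p = 0.949 with an estimated correlation. Camera with a preset correlation pointed downward.

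The smaller or little-used lists went as follows. Of 34 chemosensory genes tested, 12 were higher in salivary glands and 5 in midguts (12 and 5 adjusted over the list alone), with a median of 1.13 that did not move with the 4 members absent from midguts at their bounds. The ionotropic co-receptor gene IR76b (5.98 ± 0.76) and the odorant receptor gene Or43 (4.56 ± 0.71) were higher in salivary glands and the gustatory receptor gene Gr25 (-5.48 ± 0.57) in midguts. IR76b stood at 7.19 or 4.76 without the midgut library of infection 2 or 3, and without the gland library of infection 2 or 3 Or43 stood at 5.31 or 3.80 and Gr25 at -4.70 or -6.26. Without midguts of infection 3 the midgut count was 2. Fry gave adjusted p = 0.0318, or 0.0698 with infection as a block, and camera gave adjusted p = 0.616 with an estimated correlation. Of 7 Hox and patterning genes, 4 were higher in midguts and 1, a wingless-type gene, in salivary glands (4 and 2 adjusted over the list alone). The midgut genes were caudal, abdominal-A (AGAP004662, -4.12 ± 0.52), abdominal-B and hedgehog, and only 2 remained in the count without midguts of infection 3 or salivary glands of infection 2. The wingless-type call was lost without salivary glands of infection 2 or 3, with a count of 0 each time. This list had a median of -1.003, adjusted p = 0.0236 with fry, or 0.0711 with the block, and with camera adjusted p = 0.448 with an estimated correlation. Of 4 salivary gland secretory regulators, homothorax (AGAP002178, 1.75 ± 0.21) and X box-binding protein 1 were higher in salivary glands (2 adjusted over the list alone). Without midguts of infection 3, salivary glands of infection 2 or 3, or the mean-variance trend, the count was 1. The median was 0.80, with adjusted p = 0.0157 by fry, or 0.0869 with the block, and with camera adjusted p = 0.448 with an estimated correlation. Over the 15 lists, fry called 14, and it called 0 without midguts of infection 2, 1 without midguts of infection 3, and 5 without salivary glands of infection 2 or of infection 3.

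**Figure D3:**
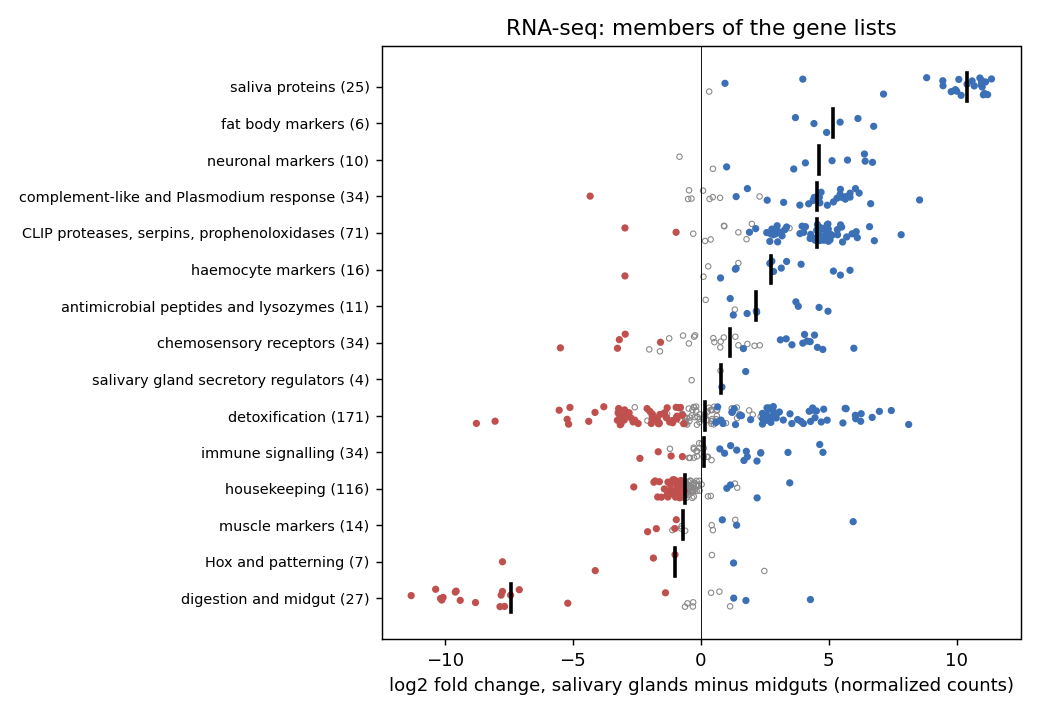
Log2 fold change (salivary glands minus midguts) of each member of the 15 gene lists in RNA-seq, with the number of genes tested in brackets. Filled points passed the adjusted threshold (blue higher in salivary glands, red higher in midguts), open points did not, and black lines are medians, from 10.40 for saliva proteins to -7.42 for digestion.

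The last comparison asked whether genes with tissue-restricted open regions were expressed more in that tissue. All 11 digestion genes with a midgut-restricted promoter region had higher RNA in midguts (17 of 27 in the whole list), among them TRYP7 (3R, 8630356 to 8630835, folds 5.88 and 6.04; log2 fold change -9.39 ± 0.96, n = 2 per tissue). All 7 saliva genes with a gland-restricted promoter region had higher RNA in salivary glands (24 of 25 in the whole list), among them D7L1 (3R, 8543672 to 8544032, folds 6.98 and 8.63; 9.78 ± 0.60) and SG2b (10.99 ± 0.24). Without the midgut library of infection 2 or 3, TRYP7 stood at -9.98 or -8.80 and D7L1 at 10.48 or 9.07, and without the gland library of infection 2 or 3 they stood at -11.04 or -7.74 and 10.48 or 9.08. With such a region, 15 of 19 CLIP and serpin genes (60 of 71 in the whole list) and the antimicrobial genes GAM1, LYSC1, LYSC4 and CEC3 (9 of 11 in the list) were higher in salivary glands. Of 24 housekeeping genes with one, 11 were higher in midguts (51 of 116 in the list) and 2 in salivary glands. Whether members with such a region differed from the rest of their list was not tested. The CEC3 call (1.81 ± 0.44) was lost without any single library, with adjusted p from 0.0815 to 0.297 (limma). Other members went against their region. With a midgut-restricted promoter region, lipophorin (2R, 11129520 to 11129644, folds 3.60 and 3.92) and CLIPB14 (2.83 ± 0.89) were higher in salivary glands. With a gland-restricted one, troponin T, a carboxypeptidase (AGAP001026, -1.38 ± 0.28), ikk2 (-0.72 ± 0.20) and hedgehog (AGAP001412, -1.003 ± 0.32) were higher in midguts. CLIPB14 stood at 2.11 or 3.56 without the midgut library of infection 2 or 3, and at 3.78 or 1.88 without the gland library of infection 2 or 3. Its call was lost without midguts of infection 2 (adjusted p = 0.106, limma) or salivary glands of infection 3 (0.181). That of hedgehog was lost without midguts of infection 2 (0.126) or 3 (0.0799) or salivary glands of infection 2 (0.209), and that of ikk2 without any single library (0.0624 to 0.152, limma). Among detoxification genes, 5 of 6 tested with a midgut-restricted promoter region were higher in midguts, such as CYP4H18 (-5.22 ± 0.69), and 1, CYP4J5 (1.59 ± 0.29), in salivary glands. With a gland-restricted promoter region, 11 of 24 were higher in salivary glands, such as CYP301A1 (6.26 ± 0.96) and ABCH1 (5.68 ± 0.35), and 5 in midguts. CYP301A1 stood at 4.75 or 7.78 without the midgut library of infection 2 or 3, and CYP4H18 at -4.29 or -6.15 without the gland library of infection 2 or 3.

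Over all genes, 83 of 179 with a midgut-restricted promoter region were higher in midguts (46.4%), against 1561 of 9706 other genes (16.1%), an odds ratio of 4.51 (95% interval 3.35 to 6.08, adjusted p = 2.9e-20, Fisher's exact test). It fell to 1.81 without the midgut list of infection 1, to 2.21 without that of infection 2 and to 2.18 with a reciprocal overlap of 50%, past the threshold each time. It was 8.75 with the upper part of each list by fold, and 7.30 and 7.14 without the salivary gland libraries of infections 2 and 3. In salivary glands, 412 of 1601 such genes were higher there (25.7%) against 23.5% of others, an odds ratio of 1.13 (1.00 to 1.28) that did not pass (adjusted p = 0.0507, Fisher's exact test). It passed with regions compared within infections (1.13, adjusted p = 0.0473) and without either gland list, either gland library or either midgut library, at odds ratios up to 1.202. It was 1.06 (p = 0.296, Fisher's exact test) without the midgut list of infection 1 and 1.02 (p = 0.778, Fisher's exact test) without that of infection 2. With a restricted region of any class the odds ratios were 1.49 (1.33 to 1.68, and 2.79 with the upper part of each list) in midguts and 1.40 (1.28 to 1.54) in salivary glands. The values for the upper part of each list include regions that may overlap weaker peaks of the other tissue. Of the 2371 genes with a midgut-restricted region of any class, 501 were higher in midguts and 701 in salivary glands. Of all 9885 genes tested, these counts were 1644 and 2355. Genes with such a region were thus called more often in both directions, so the midgut odds ratio does not show a shift towards midguts. The midgut value turned to 0.860 without the midgut list of infection 1 and to 0.961 without that of infection 2. Of the 4469 genes with a gland-restricted region of any class, 1216 were higher in salivary glands and 642 in midguts. Of the 1601 with a gland-restricted promoter region, 412 were higher in salivary glands and 205 in midguts. Against all genes tested, both groups were called more often in salivary glands and less often in midguts. Their calls in midguts were not tested. Whether the tissues differed in the odds ratios above was not tested.

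**Figure D4:**
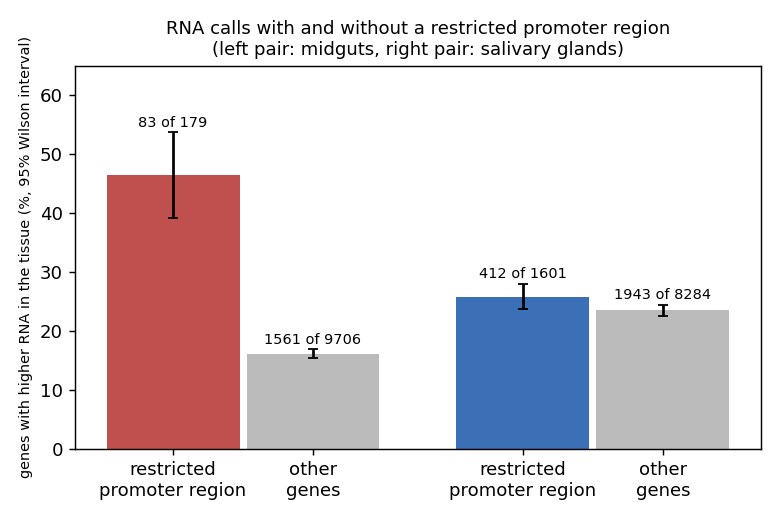
Share of genes (%) with higher RNA in midguts (left pair) or salivary glands (right pair), for genes with a tissue-restricted promoter region and for other genes, with 95% Wilson intervals. In midguts 46.4% of genes with such a region were higher there, against 16.1% of others.

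Within infection 2, where both assays were done, the highest promoter fold of a gene and its RNA level correlated across genes, with Spearman 0.371 in midguts and 0.309 in salivary glands. A promoter peak was present at 26.2% of the genes in the lowest of 4 equal bins of RNA level and at 70.9% in the highest in midguts, and at 28.9% and 73.2% in salivary glands. Genes are not independent replicates, and no p is given. The deposited table also holds the authors' calls of tissue-dependent RNA. Of the authors' midgut calls 1056 were also called here, 1 was not called and 1 was not tested, and of their salivary gland calls 2266 were called here, 46 were not and 11 were not tested. None was called in the opposite direction. A further 576 genes were called higher in midguts here, and 83 in salivary glands, where the authors give no call. The smallest size of a log2 fold change among the authors' calls, as fitted here with edgeR, was 0.90 in midguts and 0.66 in salivary glands.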

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

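The histone mark comparison, and the tests of weak signal below, were chosen after the results were seen. Of the 4095 midgut-restricted regions, 210 carried a midgut peak of H3K9me3, a mark of silent chromatin, which is 5.13% (95% interval 4.49% to 5.85%). The share was 1.93% among gland-restricted regions and 2.23% among midgut regions shared with salivary glands. This stood out as a difference between groups in a column that the report does not use. The odds ratio against gland-restricted regions was 2.75 (2.28 to 3.32, adjusted p = 3.4e-24, Fisher's exact test). The active marks H3K27ac (6.45% against 11.9%), H3K9ac (0.488% against 2.21%) and H3K4me3 (2.69% against 5.43%) were rarer at midgut-restricted than at gland-restricted regions. At shared regions these marks stood at 15.3%, 1.40% and 2.79% for midguts and at 15.0%, 1.31% and 3.04% for salivary glands. H3K9ac and H3K4me3 were thus commoner at gland-restricted than at shared gland regions, and H3K27ac was rarer, which was not tested. Regions called restricted to salivary glands can therefore carry active marks in midguts. Midgut-restricted and gland-restricted regions also differ in class, with exons at 40.4% against 4.99% and promoters at 6.03% against 15.8%. The marks were not compared within classes, so whether the difference in marks goes beyond the difference in class was not tested. With a reciprocal overlap of 50% the H3K27ac difference did not pass (odds ratio 0.970, adjusted p = 0.492, Fisher's exact test), nor did it with the upper part of each list by fold (1.08, adjusted p = 0.341). In these settings H3K9ac had odds ratios of 0.562 and 0.529 against 0.217, and H3K9me3 of 2.404 and 4.91. Without the midgut list of infection 1 or 2, H3K27ac had 0.333 or 0.332.

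Midgut-restricted regions lay in exons far more often than shared ones. Random placement over whole chromosomes is argued against for exonic midgut peaks. Of those in infection 1, 37.3% were met by a peak of infection 2, and the highest of the random placements gave 6.27%. Of all midgut peaks in infection 1, 62.4% were met. The placements did not hold peaks to exons, and restricted regions are in both lists by definition. Chance agreement of unrelated calls within exons was therefore not tested. Higher transcription in midguts than in salivary glands is argued against too. The 1222 genes with a midgut-restricted exonic region had a median log2 fold change of 0.088 and the other genes -0.04. The former had a 95% interval of 0.01 to 0.16, from 1000 bootstrap draws that take genes as independent. They did have a higher median log2 level in midguts (9.06 against 8.24), so a part of transcription that both tissues share is not excluded. Weak signal near the peak threshold stays open, as the exonic share was 48.1% in the lowest and 22.3% in the highest of 4 equal bins by fold. That highest bin began at 4.83, below the lower quartile of 5.37 for shared midgut regions, so it was not confined to strong signal. Over whole lists the exonic share was 22.7% and 18.1% in midguts of infections 2 and 1, at median folds of 4.23 and 4.90. In salivary glands of infections 1 and 2 it was 10.1% and 5.72%, at 5.53 and 6.74. Sequence preference of the transposase and a difference between the tissues or days remain untested.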

How the results depend on the processing

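Alternatives for RNA, list tests on RNA, coupling, histone marks and pathways were chosen after seeing the data. Of the results for 78 genes named with RNA values, 853 of 858 under alternative settings kept direction and side of the threshold, CLIPB14, ikk2 and hedgehog being the exceptions. So did 296 of 312 with a library left out, PPO1, CEC3 and those 3 being the exceptions. Among odds ratios under alternative settings, 52 of 56 for annotation, 46 of 72 for gene lists, 56 of 60 for coupling, 14 of 16 for marks and 23 of 24 for pathways did so. With a list or library left out these were 51 of 56, 28 of 47, 24 of 32 and 16 of 16, pathways not being run. Pathways were checked only for the 8 tests lowest in p, taken evenly from both directions. The count for pathways therefore does not carry over to the other pathway tests. Gene lists were checked only for the 12 of 30 tests that passed the threshold in the main setting or an alternative. Other values stayed close to those of the report in 57 of 112 results, and in 39 of 72 with a list or library left out. Counts of regions at named genes stayed in 53 of 80 results and 52 of 80 with a list left out. With 1 library left in a tissue, the lone sample is assumed to vary like the others. Against 3999 calls without a block, infection as a block gave 4742 with limma and 4718 with edgeR, and blocks that crossed the infections gave 3735 and 3757. Tests of each peak with their 4 alternatives, and classes from a reference annotation, were not run. Simulated changes of 1 log2 unit with 2 libraries per tissue were found in 6 of 100 genes, and depth was not varied. With 200 changed genes and the same dispersion for all, the simulation does not give the share found in the data. Except where fewer peaks or samples enter by construction, the cause was not tested.

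With the upper part of each list by fold, the lists held 21408 and 25944 peaks in midguts and 26290 and 24137 in salivary glands, with median widths of 148, 149, 239 and 266 bp, median folds of 6.54, 6.04, 9.60 and 12.9, and covered lengths of 4.37, 5.35, 8.40 and 8.37 Mb. Overlap was 63.5% between tissues, 71.3% in midguts and 86.2% in salivary glands, and restricted shares were 13.1% and 27.6%. Odds ratios were 1.25 for exons in salivary glands (p = 0.0679, Fisher's exact test), and 1.35 for introns, 1.00 for downstream sequence and 0.886 for chemosensory genes in midguts, the last 3 reversed. H3K27ac reversed to 1.08 (p = 0.341, Fisher's exact test). Spearman for peaks per gene was 0.734, promoter shares 33.9% and 43.1%, and Spearman for promoter fold and RNA 0.265 and 0.267 in midguts and salivary glands.

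With a reciprocal overlap of 50%, overlap was 29.6% between tissues, 41.6% in midguts and 60.6% in salivary glands, restricted shares were 29.7% and 53.2%, and midgut odds ratios reversed to 1.29 for introns and 0.704 for chemosensory genes. With equal list sizes, overlap was 53.0%, 57.2% and 81.7%, the gland-restricted share 32.8%, and 2 lists were under-represented. With promoter regions only, 1 list was over- and 1 under-represented, Spearman for peaks per gene was 0.672, and housekeeping genes in salivary glands reversed to 1.498. With 4 bins of peak number, 1 list was under-represented, and antimicrobial (1.28) and CLIP genes (1.257) in midguts reversed. Within infections, 0 lists were over- and 2 under-represented.

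Of the 15 lists in RNA, camera called 9 with a preset correlation and 0 with an estimated correlation, and fry called 6 with infection as a block. The odds ratio of gland-restricted promoter regions passed the threshold with a pseudocount of 0.5 (1.13), without a filter (1.25), with DESeq2 (1.13) and with regions compared within infections (1.13).

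With each list or library left out in turn, the restricted share was 19.9% to 47.1% in midguts and 40.7% to 47.1% in salivary glands. Odds ratios were 1.03 to 1.37 for 3' UTRs in salivary glands, 0.652 to 0.942 and 0.854 to 0.993 for downstream sequence in midguts and salivary glands, 0.661 to 1.25 for CLIP and 0.997 to 1.92 for chemosensory genes in midguts, and 0.681 to 1.00 for housekeeping genes in salivary glands. Over-represented lists numbered 0 to 2, and Spearman for peaks per gene was 0.665 to 0.692. Promoter shares were 39.7% to 50.9% in midguts and 51.8% to 56.7% in salivary glands. Genes higher in midguts numbered 1046 to 1350, and RNA lists past the threshold 0 to 5. The coupling odds ratio was 0.860 to 1.93 for midgut-restricted regions and 1.02 to 1.202 for gland-restricted promoter regions.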

Other observations

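The pathway tests, the test of library scaling, and the tests of carry-over and gland expression with their limits were chosen after the results were seen. Among genes the deposited table places in a pathway, energy and translation genes were frequent among those higher in midguts. Oxidative phosphorylation had 59 of 89 genes (odds ratio 8.11, adjusted p = 2.4e-18, Fisher's exact test), the ribosome 67 of 122 (odds ratio 5.05, adjusted p = 5.7e-15) and galactose metabolism 12 of 18 (odds ratio 7.54, adjusted p = 0.00046), against 21.3% of all genes with a pathway. Among genes higher in salivary glands, the breakdown of valine, leucine and isoleucine had 21 of 31 (odds ratio 12.3, adjusted p = 2.5e-09), and neuroactive ligand-receptor interaction 23 of 45 (odds ratio 6.11, adjusted p = 5.3e-07), against 15.3%. The ribosome had 0 of 122 there. Metabolic pathways as a whole were frequent in both directions, with odds ratios of 2.34 for salivary glands and 1.62 for midguts, and the latter was 1.27 with infection as a block (p = 0.0512, Fisher's exact test). In all, 50 of 214 tests passed.

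Complement-like, CLIP and serpin genes were higher in salivary glands together with fat body, haemocyte and neuronal markers. Library scaling, which moves all genes of a library alike, is argued against as the cause, since the median log2 fold change of the CLIP list lay 4.55 above that of all genes tested, and its lower quartile was 2.89. RNA from fat body and haemocytes may contribute and cannot be told apart from expression by salivary gland cells. The reason is that the fat body, haemocyte, complement-like and CLIP lists hardly differed between the salivary gland libraries. Infection 3 minus infection 2 gave a median of -0.15 for fat body, 0.24 for haemocyte, -0.03 for complement-like and 0.08 for CLIP genes, against 0.03 for all genes. Larger differences stood at neuronal (0.34), muscle (0.68), chemosensory (0.66), saliva (0.73) and digestion genes (-0.79). The medians of the remaining lists lay from -0.20 to 0.26. The most abundant fat body gene was lipophorin (Lp), at normalized counts of 107720 and 108478 in salivary glands and 1055 and 952 in midguts. Tissue and day remain open as well.

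Low levels of midgut transcripts were read in the salivary gland library of infection 2. Carry-over of midgut RNA or reads would give 1 share for all genes, and expression by salivary gland cells would give each gene its own level. Over 37 genes above 5000 in midguts and below 0.2% of that in the infection 3 gland library, the log2 ratio to midguts had an interquartile range of 0.65, but with that limit at 5% or 10% it was 2.397 or 3.45 over 64 or 78 genes. Since the limit could remove genes that gland cells express, the explanations cannot be told apart. In the other direction 28 gland genes stood at 0.0463% and 0.0604% in midguts of infections 2 and 3.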
